A study of Mus musculus with 9 samples.

How the data were processed

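Gene expression was measured in cells grown from the mouse embryonic stem cell line E14.1 (129/Ola) on the Affymetrix Mouse Exon 1.0 ST array, with 9 arrays in 3 groups of 3. Per the labels, embryonic stem cells were differentiated into cardiac progenitors, which were sorted into a fraction positive for Flk1 and Pdgfra and a fraction positive for Flk1 and negative for Pdgfra. The first fraction is named Flk1+Pdgfra+ here and the second Flk1+, as in the array titles. Cells of the first fraction were cultured onward into cTnT+ cardiomyocytes, and the labels do not state whether these were sorted for cTnT. Groups and replicate numbers were taken from the array titles. The series text states that no technical replicates were made. Nothing in the labels says that the 3 arrays of a group came from separate cultures, so p-values measure only the spread between these arrays, which may be technical in part.

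The deposited values are on the log2 scale: per the labels, the authors derived RMA expression values at the core-gene level with the Transcriptome Analysis Console software, and the submitters' processing notes name RMA and R 3.3.1. RMA subtracts background, brings the probes of all arrays to one distribution and summarises the probes of a gene, so differences between arrays in total RNA are removed. The library file version and genome build are not given in the sources used here. The table held 23332 transcript clusters with values from 1.47 to 14.2 and 0 missing values, and 3 pairs of transcript clusters had identical values on every array. Array medians lay between 7.26 and 7.53. No detection p or background signal was used here, so dim genes were not set apart from background. Folds and ranks of any gene whose lower group mean lay below the lower quartiles of the arrays (5.60 to 5.69) are therefore no exact measures. The number of arrays limits the precision.

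Gene names came from the platform's annotation table. Of the transcript clusters, 14996 carried exactly 1 gene symbol, 1019 carried several and 7317 carried none. Symbols were updated through Entrez identifiers in the RefSeq table of assembly GRCm38.p6, which matched 14941 of the 14996. The other 55 kept their older symbol. The RefSeq table was used only for names and for the chromosome of a gene. Where a gene had more than 1 transcript cluster (135 genes), the brightest over all arrays was kept and 136 were set aside, which left 14860 genes. Transcript clusters with several symbols were named for no gene, which left out Myh6, Myh7, Myl4 and Rasip1 among others.

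Differences between groups were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without trend, two-sided) on the deposited log2 values of all 9 arrays, with 1 coefficient per group, 6 residual degrees of freedom and 2.23 prior degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method over the 14860 genes, and an adjusted p under 0.05 was called. A gene was said to rise or fall only when it was called. Rank-based exact tests of 3 arrays against 3 cannot go below a two-sided p of 0.1, so none was used. The 3 comparisons were Flk1+Pdgfra+ against Flk1+, cTnT+ against Flk1+Pdgfra+ and, as a secondary comparison, cTnT+ against Flk1+. For each group, the genes higher than in both other groups were counted. The pair of comparisons behind such a set shares arrays. The count was also computed for 100 simulated data sets with unchanged groups, which cannot measure this sharing among changed genes. The product of the numbers of calls divided by the number of genes tested was given as the overlap of independent lists.

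The comparisons, tests, gene lists and alternatives, and the rule for named genes, were fixed before the data were examined, except where stated. The 24 gene lists held 441 entries, of which 377 were measured. Each list except the 3 sort markers was tested with camera at a preset correlation between genes of 0.01, and again with an estimated correlation and with fry. Camera asks whether the members change more than other genes, and fry whether they change at all. List p-values were adjusted within a comparison. Counts of members were given after adjustment over all genes tested and adjusted over the list alone. The genes named were the 3 sort markers, the 8 largest rises and 8 largest falls among called genes whose groups did not overlap (predicted genes and receptor segments left out), and up to 3 called members of each list with the largest change, or the member with the smallest p where none was called. The secondary comparison took 4 rises and 4 falls and each group-marking set took 5 genes. Genes named outside this rule are said to be so where they appear.

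Alternatives were the replicate number as a block, a filter removing the dimmest 25% of genes, quantile normalization or median centring on top of RMA, an intensity trend with robust moderation, array weights, no moderation, every transcript cluster tested, the mean of the transcript clusters of a gene, only the 6 arrays compared, and leaving out each array in turn. Added after seeing the data were a fit with replicates 1 and 2 only in both progenitor groups, a fit of the 6 progenitor arrays with the block, and 6 further gene lists. Replicates 1 and 2 were nearly alike (Pearson correlation 0.9975 in Flk1+Pdgfra+ and 0.9957 in Flk1+). P-values of fits without the third progenitor arrays therefore leave out the larger spread to those arrays. The array weights were 0.494 for the third Flk1+Pdgfra+ array, against 2.52 and 3.61 for replicates 1 and 2. For the third Flk1+ array the weight was 0.251, against 0.710 and 7.73. P-values with array weights therefore also count this larger spread for less. The labels name no batch. Whether replicate numbers pair the arrays was checked through the deviations of arrays from their group means across genes. Between the progenitor groups these correlated at 0.251, 0.325 and 0.460 for the numbers 1, 2 and 3, each above 0.1. Arrays numbered 1 and 2 correlated more highly across numbers (0.347 and 0.352). The numbers therefore set apart the third arrays but do not show that 1 and 2 pair. The main fit used no block. Equal numbers were counted as pairs only in the block and in the splits described below. Correlations with the cTnT+ arrays of the same number lay between 0.0231 and 0.0951, so no pairing was taken there.

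The calculation was tested on simulated data with 14860 genes, of which 100 were changed by 1 and 100 by 2 on the log2 scale. Normal noise with the spread of each gene was drawn independently for every gene and array. In the comparison of Flk1+Pdgfra+ with Flk1+, 75% of the smaller and 90% of the larger changes were called with the right sign and 5.71% of all calls were unchanged genes. For cTnT+ against Flk1+Pdgfra+ these shares were 70%, 95% and 6.25%. For cTnT+ against Flk1+ they were 74%, 94% and 2.33%. In the real data genes vary together and many more were called. These shares therefore check the calculation and are not error rates of the real comparisons.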

Results

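Expression of 14860 genes was measured in 3 cell populations of a cardiac differentiation from mouse embryonic stem cells, on 3 arrays each. These were mesodermal progenitors carrying the receptors Flk1 (gene Kdr) and Pdgfra, progenitors carrying Flk1 without Pdgfra, and cardiomyocytes grown from the first fraction and named for cardiac troponin T (gene Tnnt2). The series title sets out to profile cardiac progenitors and cardiomyocytes at the level of genes. Pearson correlations across genes were 0.988 to 0.998 within Flk1+Pdgfra+, 0.973 to 0.996 within Flk1+ and 0.983 to 0.987 within cTnT+. Between groups they were 0.952 to 0.975 for the progenitor populations, 0.920 to 0.928 for Flk1+Pdgfra+ and cTnT+, and 0.919 to 0.940 for Flk1+ and cTnT+; genes are not independent replicates. The first principal component held 60.2% of the variance and the second 20.5%. The first placed the cTnT+ arrays at 67.0 to 69.3 and the progenitor arrays at -38.9 to -24.8. On the second, Flk1+ replicate 3 lay at 6.53 while the other Flk1+ arrays lay at 44.8 and 45.3.

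The sort markers were read first. Pdgfra (transcript cluster 6931740) was at 11.35 ± 0.42 (log2, SD, n = 3) in Flk1+Pdgfra+ and 6.96 ± 0.40 in Flk1+, 20.9-fold higher in the former (adjusted p = 0.000327). Kdr (transcript cluster 6939241) was at 11.98 ± 0.25 and 12.30 ± 0.16, and this difference of -0.33 did not pass the test (adjusted p = 0.445, and 0.0412 with array weights). Tnnt2 (transcript cluster 6753402) was at 12.28 ± 0.38 in cTnT+, 38.4-fold above Flk1+Pdgfra+ (7.01 ± 0.37, adjusted p = 1.30e-05). Pdgfra in cTnT+ was at 11.31 ± 0.32, a difference of -0.04 from Flk1+Pdgfra+ (adjusted p = 0.925), and Kdr in cTnT+ was at 10.84 ± 0.50, 2.20-fold lower (adjusted p = 0.00575).

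**Figure D1:**
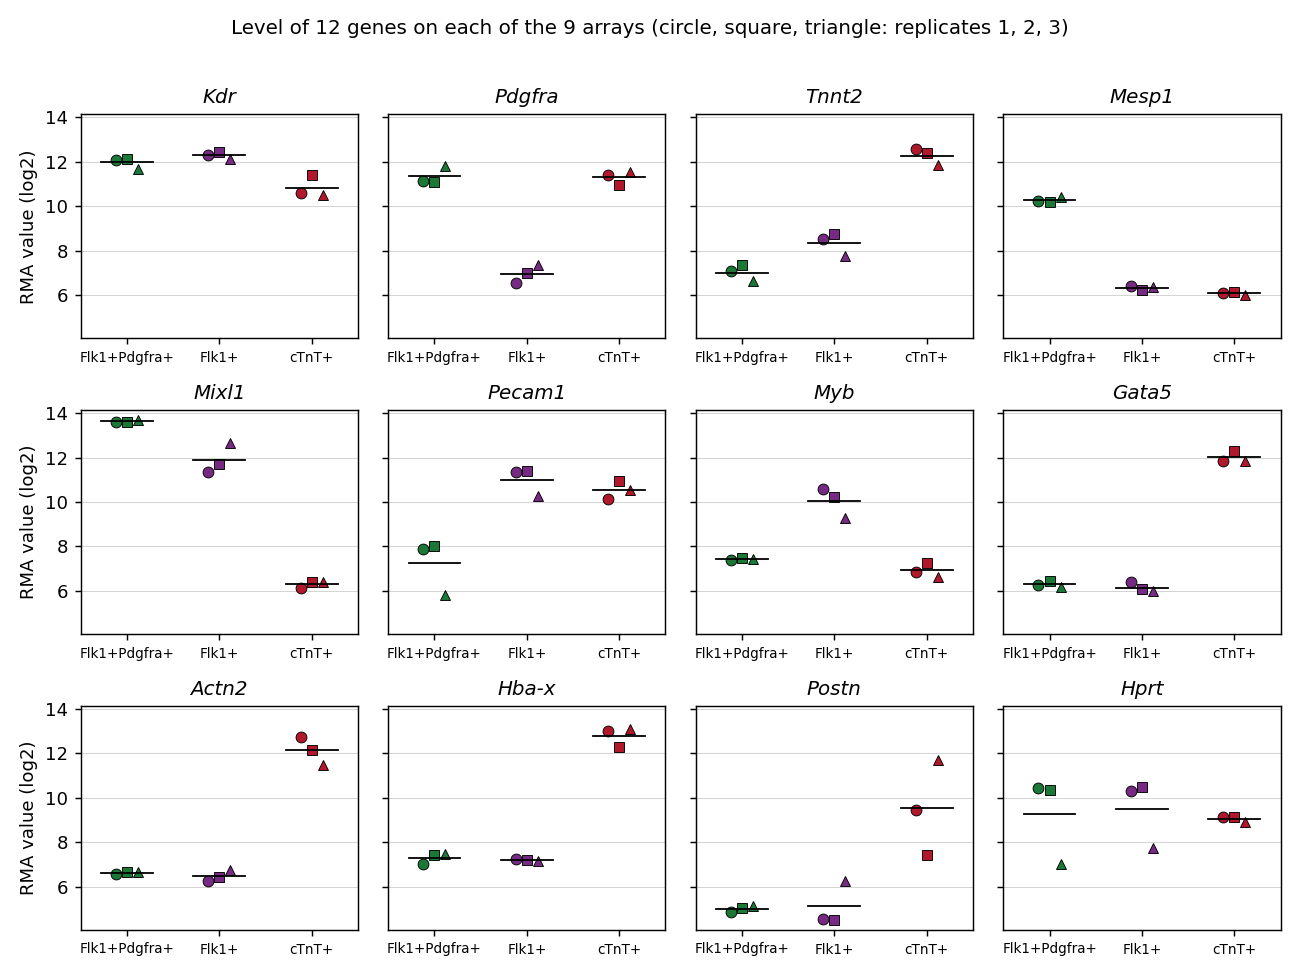
RMA value (log2) of 12 genes on each of the 9 arrays; circles, squares and triangles are replicates 1, 2 and 3 and bars are group means. Mesp1 was at 10.29 in Flk1+Pdgfra+ against 6.32 in Flk1+, Myb was at 7.43 against 10.03, and Hprt on the third array of both progenitor groups (7.02 and 7.73) lay below the other arrays.

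The comparison of Flk1+Pdgfra+ with Flk1+ asked what sets apart the progenitors that carry Pdgfra. Most measured genes of the primitive streak and of newly formed mesoderm were higher in Flk1+Pdgfra+, and most of endothelium and of blood were lower. Mesp1, a transcription factor of the earliest cardiovascular mesoderm, was at 10.29 ± 0.11 against 6.32 ± 0.09 (SD, n = 3 each), 15.7-fold higher (adjusted p = 7.62e-07). Tek, the endothelial angiopoietin receptor, was at 7.90 ± 1.24 against 11.95 ± 0.32, 16.6-fold lower (adjusted p = 0.00342). In all, 690 genes were higher and 872 lower by limma with an adjusted p under 0.05, which is 10.5% of the genes tested, and 648 of these changed at least 2-fold, 197 upward and 451 downward.

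Of 16 measured genes of the primitive streak and nascent mesoderm, 11 rose and 0 fell (11 and 0 adjusted over the list alone, median 1.42). Besides Mesp1 these included Lhx1, 11.9-fold higher (11.91 ± 0.82 against 8.33 ± 1.66, adjusted p = 0.0239), and Snai1, a driver of the epithelial-to-mesenchymal transition, 7.01-fold higher (adjusted p = 0.00664). The list passed camera (adjusted p = 5.40e-08, and adjusted p = 0.357 with an estimated correlation). Of 19 Wnt pathway genes 6 rose and 1 fell (10 and 1 over the list alone, median 1.03, adjusted p = 0.0121, and 0.357 with an estimated correlation). The ligands Wnt5a and Wnt2 were 7.03-fold and 3.53-fold higher and the target Sp5 was 4.54-fold higher, while the receptor Fzd10 fell by 1.55 on the log2 scale. With progenitor replicates 1 and 2 only, Wnt2 did not pass limma (1.38, adjusted p = 0.0551). Of 18 BMP pathway genes 3 rose and 0 fell (9 and 0 over the list alone, median 0.75, adjusted p = 0.00987, and 0.557 with an estimated correlation): Msx1 (6.11-fold), Bmper (2.70-fold) and the BMP antagonist Nog (2.08-fold). Nog was at 5.24 in Flk1+, below the lower quartiles of the arrays (5.60 to 5.69), so its fold is no exact measure. With the replicate number as a block, Msx1 did not pass (adjusted p = 0.0530). Without the third array of both groups 9 BMP genes rose and 0 fell (median 1.01, adjusted p = 4.37e-06). On those arrays the BMP median was shifted by -0.48 in Flk1+Pdgfra+ and 0.42 in Flk1+. The streak median was shifted by 0.35 and 0.90.

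Of 18 endothelial genes 16 fell and 0 rose (17 and 0 adjusted over the list alone, median -2.96), among them Pecam1, which was 13.6-fold lower (adjusted p = 0.00644), and Sox7, which was 12.9-fold lower (adjusted p = 0.0121). Of 17 haematopoietic genes 9 fell and 0 rose (12 and 0 over the list alone, median -1.58). They included Ikzf1 (6.38-fold lower), the platelet integrin Itga2b (6.17-fold lower) and Myb (6.09-fold lower, 7.43 ± 0.04 against 10.03 ± 0.67). Camera gave adjusted p = 3.16e-16 for the endothelial list and 1.06e-09 for the haematopoietic list, with adjusted p = 0.329 for each with an estimated correlation. On the third arrays these genes were lower than on the first and second: the endothelial median was shifted by -1.21 in Flk1+Pdgfra+ and -0.75 in Flk1+, and the haematopoietic median by -0.24 and -0.87. Of 10 glycolysis genes 3 fell and 1 rose (5 and 1 over the list alone, median -0.28, adjusted p = 0.0106, and 0.557 with an estimated correlation). The kinases Pdk1, Pfkp and Hk1 were 3.66-fold, 2.76-fold and 2.29-fold lower, and Pkm was higher by 0.55. The glycolysis list lost its call without Flk1+Pdgfra+ replicate 3 (adjusted p = 0.0506).

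Among the other called genes with the largest falls were Samsn1, 20.1-fold lower (6.51 ± 1.42 against 10.84 ± 0.33, adjusted p = 0.00572), Ctse (19.1-fold), Gimap4 (18.3-fold), Hapln1 (17.1-fold), the endothelial adhesion receptor Adgrl4 (16.8-fold, adjusted p = 0.0404) and Myct1 (14.9-fold). Large rises were seen for the Wnt antagonist Frzb, 20.4-fold higher (11.41 ± 0.89 against 7.06 ± 2.08, adjusted p = 0.0231), the Nodal co-receptor Tdgf1, 18.7-fold higher (13.07 ± 0.34 against 8.84 ± 2.36, adjusted p = 0.0448), the lateral mesoderm factor Foxf1 (12.3-fold, adjusted p = 0.0211) and Otx2 (9.87-fold, adjusted p = 0.0371). Tdgf1 did not pass with the replicate block (adjusted p = 0.0616). Single arrays moved several differences: without Flk1+ replicate 3 those of Frzb and Tdgf1 were 5.55 each and that of Otx2 was 4.32 on the log2 scale, and without Flk1+Pdgfra+ replicate 3 that of Adgrl4 was -2.79. Over all alternatives Lhx1 ran from 3.03 to 4.53, Foxf1 from 3.06 to 4.45 and Samsn1 from -4.87 to -3.52. Sox7 ran from -4.17 to -2.87, Tek from -4.47 to -3.34 and Pecam1 from -4.16 to -3.05. The SDs above 1 in Flk1+ come with the third array set apart: Flk1+ replicate 3 held Pou5f1 at 10.73 and Nanog at 10.99, against 6.69 to 7.41 and 6.21 to 6.43 on the other Flk1+ arrays.

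The remaining lists did not pass camera. Of 18 cardiac transcription factors 3 rose and 1 fell (6 and 1 over the list alone, median 0.47, adjusted p = 0.258): Isl1 was 4.04-fold, Gata4 2.15-fold and Gata6 1.84-fold higher, and Mef2c was 3.09-fold lower. Of 18 pluripotency genes Tdgf1 rose and Dppa4 fell (10.6-fold lower, 2 and 2 over the list alone, median 0.26, adjusted p = 0.623). Without the third array of both progenitor groups 7 rose and 1 fell (adjusted p = 0.000707). Dppa4 was at 5.11 in Flk1+Pdgfra+, below the lower quartiles of the arrays (5.60 to 5.69), so its fold is no exact measure. Of 12 epithelial genes 0 were called (0 and 0 over the list alone, median 0.12, adjusted p = 0.876, Esrp1 1.67, adjusted p = 0.235). Esrp1 passed with array weights (2.79, adjusted p = 0.000132), without Flk1+ replicate 3 (2.81, 0.000146) and with progenitor replicates 1 and 2 only (2.89, 0.000334). Without the third progenitor arrays 7 epithelial genes rose (adjusted p = 3.77e-05). Replicates 1 and 2, which remain there, were nearly alike, so such p-values leave out the spread to the third arrays. In the paraxial and lateral mesoderm list 1 of 16 rose, Foxf1 (1 and 0 over the list alone, median 0.23, adjusted p = 0.115), and in the neural list 1 of 13, Otx2 (1 and 0 over the list alone, median 0.21, adjusted p = 0.184). These last 4 lists, pluripotency (0.00108), epithelial (6.10e-05), paraxial (0.0383) and neural (0.0132), passed when Flk1+ replicate 3 was left out. Array weights, which count the third progenitor arrays for less, brought the epithelial (0.0473), paraxial (0.0318) and neural (0.0318) lists past the threshold.

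In the sarcomere list 0 of 15 genes were called (0 over the list alone, median 0.096, adjusted p = 0.921), as were 0 of 19 for calcium handling and ion channels (0 over the list alone, median 0.077, adjusted p = 0.826). In the former, Myl7 differed by 1.75 (adjusted p = 0.117). It passed in the fit of the 6 progenitor arrays with the replicate block (0.0246) and with progenitor replicates 1 and 2 only (0.0346), both chosen after seeing the data, and with array weights (0.00590). In the latter, Gja1 differed by 1.00 (adjusted p = 0.0654, and 0.0126 with the replicate block, 0.0342 with median centring, 0.000134 with array weights, 0.00638 without Flk1+ replicate 3 and 0.00916 with progenitor replicates 1 and 2 only). None of 14 atrial, ventricular and pacemaker genes was called (0 over the list alone, median 0.27, adjusted p = 0.452, Tbx3 1.26, adjusted p = 0.0878, and 0.000337 with array weights, 0.0473 with progenitor replicates 1 and 2 only and 0.0371 without cTnT+ replicate 2), and none of 11 endoderm genes (0 over the list alone, median 0.16, adjusted p = 0.749, Sox17 -1.01, adjusted p = 0.0612, and 0.0287 with the replicate block, 0.0491 with the filter on dim genes, 0.000187 with array weights, 0.0201 without Flk1+ replicate 3 and 0.0400 with progenitor replicates 1 and 2 only). Without the third progenitor arrays 4 chamber genes (adjusted p = 0.149) and 3 calcium handling genes (0.608) rose. The mitochondrial list had 1 riser of 18, Cpt2 (1.58-fold, 1 and 0 over the list alone, median 0.16, adjusted p = 0.401). The cell cycle list had 1 riser of 25, Ccne1 (1.76-fold, 1 and 0 over the list alone, median 0.041, adjusted p = 0.623). In the smooth muscle list Mylk fell (2.57-fold lower, 0 and 1 over the list alone), with a median of 0.14, a mean of -0.068 and a downward test (adjusted p = 0.401). Sparc fell in the matrix list (1.65-fold lower, 0 and 1 over the list alone, median -0.077, adjusted p = 0.401).

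Of 13 Notch pathway genes Dll3 and Hes1 rose and Dll4 and Mfng fell (2 and 2 over the list alone). The median was 0.13 and the mean -0.038, with camera downward (adjusted p = 0.826) and fry upward (adjusted p = 0.699). Dll3 was 5.49-fold higher, and Dll4, an endothelial ligand, 5.30-fold lower. Of 32 Hox genes Hoxd13 rose (1.43-fold, 0 over the list alone, median 0.0039, mean -0.067, downward test with adjusted p = 0.591), a call lost with the replicate block (adjusted p = 0.0588). Of 15 stress and immediate early genes 3 fell (3 over the list alone, median -0.069, adjusted p = 0.283): Atf3 (4.73-fold lower), Junb (1.56-fold lower) and Fosl1 (1.53-fold lower). Of 9 reference genes Tbp rose by 0.36 and B2m fell by 0.70 (1 and 1 over the list alone, median -0.075, adjusted p = 0.457), and Tnnt2 was 2.54-fold lower in Flk1+Pdgfra+ (adjusted p = 0.0289). Gata6, Fzd10, Pkm and Hes1 were named after their values were seen.

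In limma, the counts of this comparison depended on single arrays. The 690 higher genes became 214 without Flk1+Pdgfra+ replicate 1, 218 without replicate 2 and 418 without replicate 3, and 286, 203 and 1306 without Flk1+ replicates 1, 2 and 3; the 872 lower genes became 503 and 517 without Flk1+Pdgfra+ replicates 1 and 2 and 461 without Flk1+ replicate 2. The 648 genes with a 2-fold change became 392 without Flk1+ replicate 2 and 1022 without Flk1+ replicate 3, and the 6 lists became 10 without the latter. With replicates 1 and 2 only in both progenitor groups, a setting chosen after seeing the data, 1148 genes were higher, 945 lower and 1024 changed 2-fold. Array weights gave 4521 higher, 3017 lower and 1184 with a 2-fold change. The weights of the third progenitor arrays were low (0.494 and 0.251), so these counts give the spread to those arrays less weight. Of 47 named genes that were called, 25 stayed called whichever array was left out. The other 22, among them Lhx1, Frzb, Otx2, Foxf1, Tdgf1, Msx1, Gata4, Sox7, Dll4 and Tnnt2, lost the call without at least 1 array: 21 of them without Flk1+ replicate 2 (adjusted p 0.0525 to 0.158), 19 without Flk1+Pdgfra+ replicate 1 (0.0501 to 0.148), 19 without its replicate 2 (0.0503 to 0.144), 11 without its replicate 3 (0.0501 to 0.121), 16 without Flk1+ replicate 1 (0.0503 to 0.125) and 2 without Flk1+ replicate 3 (0.0727 and 0.0790). Without cTnT+ replicates 1, 2 and 3, which enter only the shared spread, 6, 5 and 6 lost it (0.0528 to 0.0648).

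**Figure D2:**
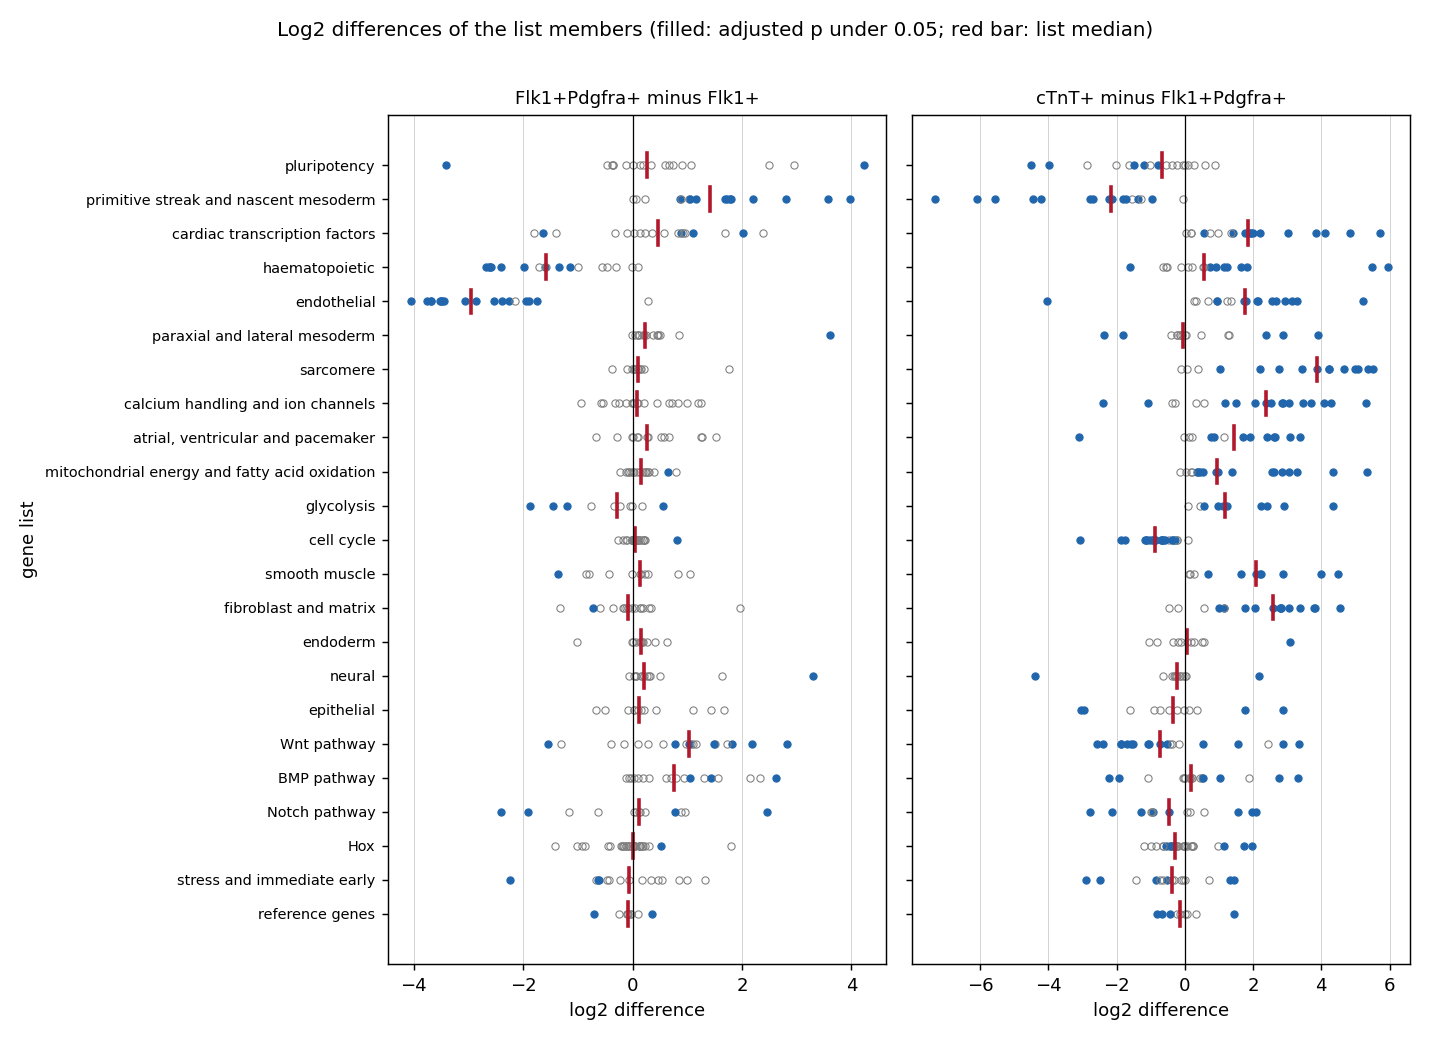
Log2 differences of the measured members of 23 gene lists, Flk1+Pdgfra+ minus Flk1+ on the left and cTnT+ minus Flk1+Pdgfra+ on the right; filled points have adjusted p under 0.05 and red bars are list medians. Endothelial genes had a median of -2.96 on the left and 1.76 on the right, and sarcomere genes 0.096 and 3.86.

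The comparison of cTnT+ with Flk1+Pdgfra+ followed the same lineage from the progenitor to the cardiomyocyte culture. Most measured genes of the contractile apparatus, of calcium handling and of oxidative metabolism rose, while most of the primitive streak and of cell division fell. Actn2, the alpha-actinin of the Z-disc, rose from 6.62 ± 0.07 to 12.13 ± 0.63 (SD, n = 3 each), 45.5-fold (adjusted p = 7.96e-06). Mixl1, a homeobox factor of the primitive streak, fell from 13.63 ± 0.05 to 6.31 ± 0.15, 160.2-fold (adjusted p = 4.54e-06). In all, 3348 genes were higher and 2778 lower by limma with an adjusted p under 0.05, 41.2% of the genes tested, and 2319 changed at least 2-fold, 1604 upward and 715 downward. More genes were lower than higher with arrays centred on their medians (2737 higher, 3187 lower) and with quantile normalization (3062 and 3140).

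Of 15 sarcomere genes 12 rose and 0 fell (12 and 0 adjusted over the list alone, median 3.86), with Tnni1, the slow skeletal troponin I of the embryonic heart, 40.9-fold higher (adjusted p = 2.93e-06) and the ventricular light chain Myl2 33.7-fold higher. Calcium handling and ion channels had 13 risers and 2 fallers of 19 (13 and 2 over the list alone, median 2.39). The sodium-calcium exchanger Slc8a1 was 39.3-fold higher, the ryanodine receptor Ryr2 19.6-fold and Hrc 16.9-fold, while Kcnj3 fell by 2.40 and Gja1 by 1.07 on the log2 scale. Of 18 cardiac transcription factors 12 rose and 0 fell (12 and 0 over the list alone, median 1.84), led by Gata5 (53.1-fold, 6.29 ± 0.12 to 12.02 ± 0.26), Mef2c (28.6-fold) and Tbx5 (17.1-fold). Atrial, ventricular and pacemaker genes had 9 risers and 1 faller of 14 (10 and 1 over the list alone, median 1.43), with Lbh 10.3-fold and Bmp10 8.39-fold higher and the conduction-system repressor Tbx3 8.63-fold lower. Camera gave adjusted p = 6.98e-07 for the sarcomere, 6.37e-05 for calcium handling, 1.73e-05 for the transcription factors and 0.00553 for the chamber genes. With an estimated correlation these were adjusted p = 0.244, 0.244, 0.236 and 0.375.

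Of 18 genes of mitochondrial energy and fatty acid oxidation 14 rose and 0 fell (14 and 0 over the list alone, median 0.94, adjusted p = 8.05e-06, and 0.235 with an estimated correlation). Ppargc1a, a coactivator of mitochondrial biogenesis, rose from 4.65 ± 0.12 to 9.98 ± 0.21 (adjusted p = 2.79e-07). Its rise of 40.2-fold is no exact measure, since 4.65 lay below the lower quartiles of the arrays (5.60 to 5.69). The lipase Lpl rose 20.2-fold and the fatty acid binding protein Fabp3 9.81-fold. Glycolysis genes moved the same way, with 8 risers and 0 fallers of 10 (8 and 0 over the list alone, median 1.17, adjusted p = 3.22e-05, and 0.244 with an estimated correlation). The kinase Pdk1 was 20.2-fold higher, Hk1 7.52-fold and Pfkp 5.35-fold. Cell cycle genes fell: 21 of 25, with 0 risers (23 and 0 over the list alone, median -0.86, adjusted p = 1.49e-08, and 0.292 with an estimated correlation), including Myc (8.38-fold lower), Ccne1 (3.66-fold) and Cdc6 (3.36-fold).

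Of 16 streak and nascent mesoderm genes 13 fell and 0 rose (15 and 0 over the list alone, median -2.18, adjusted p = 5.28e-08, and 0.246 with an estimated correlation), including Eomes (68.0-fold lower, adjusted p = 4.97e-06) and Lhx1 (47.0-fold lower). Of 18 pluripotency genes 5 fell and 0 rose (5 and 0 over the list alone, median -0.67, adjusted p = 0.0362, and 0.584 with an estimated correlation): Pou5f1 (22.6-fold lower), Nanog (15.7-fold lower), Lin28a (2.83-fold lower), Zfp42 (2.28-fold lower) and Fgf4 (1.72-fold lower). Of 19 Wnt pathway genes 11 fell and 4 rose (12 and 5 over the list alone, median -0.72, adjusted p = 0.0362, and 0.308 with an estimated correlation). Sp5 fell 5.90-fold, while the antagonist Sfrp1 rose 10.3-fold, the receptor Fzd4 7.34-fold, Wnt2 2.97-fold and Wnt11 1.45-fold. Without the third progenitor arrays 11 of the 18 pluripotency genes fell (adjusted p = 0.00182). The pluripotency list lost its call without cTnT+ replicate 3 (0.0603), and the Wnt list without cTnT+ replicate 2 (0.0581) or 3 (0.0603). Each also lost it with the filter on dim genes (0.109 and 0.0676) and without moderation (0.0664 each).

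Some genes of lists named for other cell types were higher in cTnT+ than in Flk1+Pdgfra+, which does not show that those cells were present. Of 18 endothelial genes 11 rose and 1 fell (12 and 1 over the list alone, median 1.76, adjusted p = 0.00207, and 0.525 with an estimated correlation), with Emcn 37.2-fold and Pecam1 9.86-fold higher and the early endothelial factor Etv2 16.5-fold lower. Of 17 fibroblast and matrix genes 13 rose and 0 fell (13 and 0 over the list alone, median 2.57, adjusted p = 0.000206, and 0.450 with an estimated correlation), with Postn 23.3-fold higher (9.53 ± 2.14 against 4.99 ± 0.13; 4.54 on the log2 scale, and 3.45 without cTnT+ replicate 3 and 5.59 without its replicate 2), Col6a1 13.9-fold higher and Tcf21 higher by 3.82 on the log2 scale. Of 11 smooth muscle genes 8 rose and 0 fell (8 and 0 over the list alone, median 2.10, adjusted p = 0.00253, and 0.244 with an estimated correlation), with Des 22.6-fold, Acta2 16.0-fold and Tagln 7.39-fold higher. Of 17 haematopoietic genes 8 rose and 1, Runx1, fell by 1.60 (8 and 1 over the list alone, median 0.56, adjusted p = 0.0785). The embryonic globins led this list, with Hbb-y 61.8-fold higher and Hba-x 44.8-fold higher (12.79 ± 0.45 against 7.30 ± 0.24), beside Gata1 (3.55-fold). In Flk1+Pdgfra+ Hbb-y (5.26) and Postn (4.99) lay below the lower quartiles of the arrays (5.60 to 5.69), so their folds and ranks are no exact measures. The haematopoietic list passed without Flk1+Pdgfra+ replicate 2 (0.0354), with arrays centred on their medians (0.0434) and with only the 6 arrays compared (0.0488). All 12 sarcomere risers peaked on cTnT+ replicate 1, 9 of the 11 endothelial risers on replicate 2, and all 13 matrix and 6 of the 8 haematopoietic risers on replicate 3. Of the 8 smooth muscle risers 5 peaked on replicate 1, as the sarcomere genes did.

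Other called genes with the largest rises were Plppr5 (80.3-fold, 4.37 ± 0.26 to 10.69 ± 0.93, adjusted p = 1.65e-05), Tecrl (77.5-fold), Ankrd1, a cardiac ankyrin repeat protein (64.5-fold), Smyd1, a histone methyltransferase of striated muscle (56.8-fold), Edil3 (50.9-fold) and Igfbp5 (45.9-fold). The largest falls included Cyp26a1, which degrades retinoic acid (58.7-fold, 11.89 ± 0.35 to 6.01 ± 0.32, adjusted p = 2.93e-06), Fgf5 (24.6-fold), Wnt3 (21.8-fold) and Otx2 (20.9-fold). Fgf5 fell by 4.62 on the log2 scale, with a difference of -3.71 without Flk1+Pdgfra+ replicate 3. In cTnT+ Fgf5 lay at 5.47, 5.04 and 5.73, with a mean below the lower quartiles of the arrays, so its fold and rank are no exact measures. Plppr5 (4.37) and Tecrl (3.56) lay in Flk1+Pdgfra+ below the lower quartiles of the arrays (5.60 to 5.69) and were not shown to be above background, so their folds and ranks are no exact measures, and Tecrl was removed by the filter on dim genes.

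The remaining lists did not pass camera. BMP pathway genes numbered 4 risers and 2 fallers of 18 (3 and 2 over the list alone, median 0.18, adjusted p = 0.453): Id2 was 10.04-fold, Smad9 6.84-fold, Bambi 2.06-fold and Nog 1.45-fold higher, and Msx1 was 4.67-fold and Bmper 3.84-fold lower. In the Notch pathway 3 rose and 5 fell of 13 (3 and 5 over the list alone, median -0.46, adjusted p = 0.273): Dll4 (4.27-fold), Mfng (3.93-fold) and Jag2 (2.97-fold) were higher and Dll3 (6.93-fold), Hes1 (4.38-fold), Nrarp (2.45-fold), Notch3 (1.90-fold) and Notch2 (1.37-fold) lower. Of 32 Hox genes 3 rose and 2 fell (1 and 0 over the list alone, median -0.28, adjusted p = 0.264): Hoxb4 (3.94-fold), Hoxb2 (3.33-fold) and Hoxb5 (2.21-fold) were higher and Hoxa10 (1.47-fold) and Hoxd13 (1.32-fold) lower. Hoxb5 lost its call under quantile normalization (0.0922), median centring (0.0801) and the replicate block (0.0630) and without moderation (0.0979). Of 16 paraxial and lateral mesoderm genes Snai2 (15.0-fold), Prrx2 (7.38-fold) and Tbx18 (5.19-fold) rose and Foxf1 (5.20-fold) and Dll1 (3.48-fold) fell (2 and 0 over the list alone). Their median was -0.042 and their mean 0.43, and the test pointed upward (adjusted p = 0.816).

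Of 15 stress and immediate early genes 2 rose, Gadd45b (2.70-fold) and Ddit3 (2.51-fold), and 4 fell, Fos (7.48-fold), Hsph1 (5.66-fold), Jun (1.79-fold) and Junb (1.44-fold, 2 and 4 over the list alone, median -0.37, adjusted p = 0.2496). Of 12 epithelial genes Krt19 (7.34-fold) and Ocln (3.37-fold) rose and Esrp1 (8.28-fold) and Epcam (7.71-fold) fell (2 and 2 over the list alone, median -0.34, adjusted p = 0.575). In the neural list Pax6 rose (4.49-fold) and Otx2 fell (1 and 1 over the list alone, median -0.23, adjusted p = 0.264), and in the endoderm list Dab2 rose (8.52-fold, 1 and 0 over the list alone, median 0.059, adjusted p = 0.812). Of 9 reference genes B2m rose 2.70-fold, and Polr2a (1.77-fold), Tbp (1.58-fold) and Rplp0 (1.36-fold) fell (1 and 3 over the list alone, median -0.15, adjusted p = 0.388). Members of lists named here beyond the 3 largest changes were chosen after their values were seen.

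Of 77 named genes that were called in this comparison, 69 stayed called whichever array was left out. The other 8 were Acta2, Dll4, Epcam, Foxf1, Hoxb2, Hoxb5, Msx1 and Nanog. Without Flk1+Pdgfra+ replicate 1, 2 or 3 the call ended for 6, 6 and 4 of them (adjusted p 0.0516 to 0.122), without cTnT+ replicate 1, 2 or 3 for 5, 4 and 5 (0.0510 to 0.136), without Flk1+ replicate 1 for Foxf1 (0.0501) and without Flk1+ replicate 2 for Hoxb5 (0.0578). Centring the arrays on their medians moved the median of all genes in this comparison from 0.0043 to -0.11.

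The secondary comparison of cTnT+ with Flk1+ set the cardiomyocyte culture against the progenitors from which it was not grown. Most muscle genes were again higher in cTnT+, while 8 of 18 endothelial genes fell and 1 rose, against 1 and 11 in the comparison with Flk1+Pdgfra+; the list had no call in either with an estimated correlation (adjusted p = 0.390 and 0.525). Tnnt2 was 15.1-fold higher (adjusted p = 5.73e-05), Pdgfra 20.3-fold higher (adjusted p = 2.52e-05) and Kdr 2.76-fold lower (adjusted p = 0.00180). Plppr5 (72.9-fold), Tecrl (67.8-fold), the atrial light chain Myl7 (63.2-fold) and Slc8a1 (62.1-fold) had the largest rises. In Flk1+ Plppr5 (4.50) and Tecrl (3.76) lay below the lower quartiles of the arrays (5.60 to 5.69), so their folds and ranks are no exact measures. Mixl1 (48.4-fold), Cyp26a1 (45.5-fold), Eomes (19.9-fold) and the Wnt target Lgr5, which fell by 4.52 on the log2 scale, had the largest falls. By limma with an adjusted p under 0.05, 3363 genes were higher and 2464 lower, 39.2% of those tested, with 2099 changed at least 2-fold (1509 and 590). More were lower than higher with arrays centred on their medians (2709 higher, 2713 lower) and over every transcript cluster (3756 and 4076).

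Lists higher in cTnT+ than in Flk1+ were cardiac transcription factors (14 of 18 rose, adjusted p = 2.32e-06, and 0.162 with an estimated correlation), sarcomere (12 of 15, 3.13e-07 and 0.337), calcium handling (12 of 19, 9.78e-06 and 0.221), chamber genes (10 of 14 with Tbx3 falling, 0.00162 and 0.348), mitochondrial energy (15 of 18, 3.13e-07 and 0.124) and glycolysis (9 of 10, 0.000178 and 0.348). Smooth muscle (6 of 11 with Mylk falling, adjusted p = 0.0331, and 0.348 with an estimated correlation), matrix (12 of 17, 0.000994 and 0.390) and BMP pathway (8 of 18, 0.0187 and 0.390) were higher as well. Adjusted over the list alone, the risers of these 9 lists numbered 14, 13, 12, 12, 16, 9, 7, 13 and 9. Lower in cTnT+ were cell cycle (20 of 25 fell, adjusted p = 5.49e-09, and 0.348 with an estimated correlation), streak and nascent mesoderm (7 of 16, 0.00103 and 0.390), endothelial (8 of 18 with Emcn rising, 0.00117 and 0.390) and haematopoietic (10 of 17, 0.0401 and 0.495). In the last, Hbb-y, Hba-x and Klf1 rose. Without the third progenitor arrays 14 of 18 endothelial genes fell (adjusted p = 6.44e-06). Stress and immediate early genes were also lower (5 of 15, adjusted p = 0.0347, and 0.495 with an estimated correlation): Atf3, Hsph1, Jun, Junb and Fosl1 fell, and Gadd45b, Gadd45a and Ddit3 rose. The fallers of these 5 lists numbered 21, 7, 8, 10 and 6 adjusted over the list alone.

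The pluripotency list did not pass (Dppa4, Dppa2, Zfp42 and Esrrb fell and Dppa5a rose, 3 and 0 over the list alone, median -0.47, adjusted p = 0.0557). The Notch list (Hes1, Nrarp, Notch3 and Notch2 fell, Jag2 rose, 4 and 1 over the list alone, median -0.34, adjusted p = 0.112), Hox (Hoxb4 rose, 0 over the list alone, median -0.15, adjusted p = 0.135), paraxial mesoderm (Snai2, Prrx2, Tbx18 and Osr1 rose, 3 over the list alone, median 0.19, adjusted p = 0.135) and reference genes (Polr2a, Rplp0, Tbp and Ywhaz fell, B2m rose, 4 and 1 over the list alone, median -0.26, adjusted p = 0.151) did not pass. The Wnt (Sfrp1, Wnt2, Sfrp5 and Fzd7 rose, Fzd10 and Rspo3 fell, 4 and 2 over the list alone, median 0.057, adjusted p = 0.974), endoderm (Dab2 and Apoa2 rose, 1 over the list alone, median 0.072, adjusted p = 0.733) and neural lists (Pax6 rose, 1 over the list alone, median 0.030, adjusted p = 0.974) did not pass either. In the epithelial list Krt19 rose (1 over the list alone), with median -0.38, camera downward (adjusted p = 0.685) and fry upward (adjusted p = 0.988). The haematopoietic list lost its call without Flk1+ replicate 1 (0.110) or 2 (0.0504) or cTnT+ replicate 2 (0.0553), and the stress list without Flk1+ replicate 3 (0.166) or cTnT+ replicate 2 (0.0541) or 3 (0.0581). The pluripotency list passed with the replicate block (0.0378) and without Flk1+ replicate 1 (0.0106) or 2 (0.0143) or cTnT+ replicate 1 (0.0499), and Hox without Flk1+ replicate 2 (0.0212). With the filter on dim genes the haematopoietic (0.0770), stress (0.0742), smooth muscle (0.0770) and BMP (0.0599) lists lost their calls. Members named for this comparison's lists were chosen after their values were seen. With camera at the preset correlation 6, 13 and 14 lists were called in the 3 comparisons in the order given here, and with an estimated correlation 0 in each. Fry's test for change in either direction called 14, 23 and 20. Fry does not set members against other genes, of which 41.2% and 39.2% were called in the comparisons with cTnT+. Its calls of either kind there are therefore not particular to a list. Even the reference genes passed the test for either direction there (adjusted p = 2.69e-08 and 2.07e-07). Fry's test for change in one direction called 5, 16 and 16. It did not call BMP (0.0565) and glycolysis (0.0769) between the progenitors, pluripotency (0.100) between cTnT+ and Flk1+Pdgfra+, or haematopoietic (0.262) and stress genes (0.0665) between cTnT+ and Flk1+. Beyond camera it called paraxial mesoderm in each comparison (0.0123, 0.0285 and 0.000557), Notch (0.0285 and 0.0255) and reference genes (0.00555 and 0.00244) in both comparisons with cTnT+, haematopoietic genes against Flk1+Pdgfra+ (0.00774) and endoderm against Flk1+ (0.0240).

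Genes higher in a population than in both others numbered 383 for Flk1+Pdgfra+, 324 for Flk1+ and 2498 for cTnT+. Flk1+Pdgfra+ was marked by Mesp1, at least 15.7-fold above either other population, Lhx1 (11.9-fold), Otx2 (9.87-fold), Gna14 (6.65-fold) and the chemokine receptor Cxcr4 (6.45-fold, 10.77 ± 0.05, SD, n = 3). Flk1+ was marked by Samsn1 (by at least 3.83 on the log2 scale), Tfec (12.7-fold), Nrip3 (12.3-fold), the endothelial and blood factor Fli1 (10.6-fold, 12.15 ± 0.24) and Dppa4 (6.98-fold). The markers of cTnT+ were Plppr5 (72.9-fold), Tecrl (67.8-fold), Smyd1 (56.8-fold), Gata5 (53.1-fold) and Hbb-y (49.9-fold). In both progenitor groups Plppr5, Tecrl and Hbb-y lay below the lower quartiles of the arrays (5.60 to 5.69), so their folds and ranks are no exact measures. Each fold is the smaller of the pair of differences. Of these 15 genes 4 failed under some alternative. Lhx1 failed without any 1 of the Flk1+Pdgfra+ arrays or Flk1+ replicates 1 and 2 and without moderation, and Otx2 failed in these settings and without any 1 of the cTnT+ arrays. Fli1 failed without Flk1+ replicate 2, and Dppa4 without replicate 2 of either progenitor group and with progenitor replicates 1 and 2 only. Data simulated without changes gave 0 such genes (highest of 100 simulations 0), which the adjustment brings about when no gene changes. The simulation therefore does not measure what shared arrays add among changed genes. Independent lists would overlap in 129, 145 and 758 genes. With 3 arrays per group the shared arrays could not be divided, so part of the excess may come from them. The Flk1+Pdgfra+ set held 127, 130 and 249 genes without Flk1+Pdgfra+ replicates 1, 2 and 3 and 167 and 131 without Flk1+ replicates 1 and 2. The Flk1+ set held 201 and 210 without Flk1+Pdgfra+ replicates 1 and 2 and 161 without Flk1+ replicate 2.

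**Figure D3:**
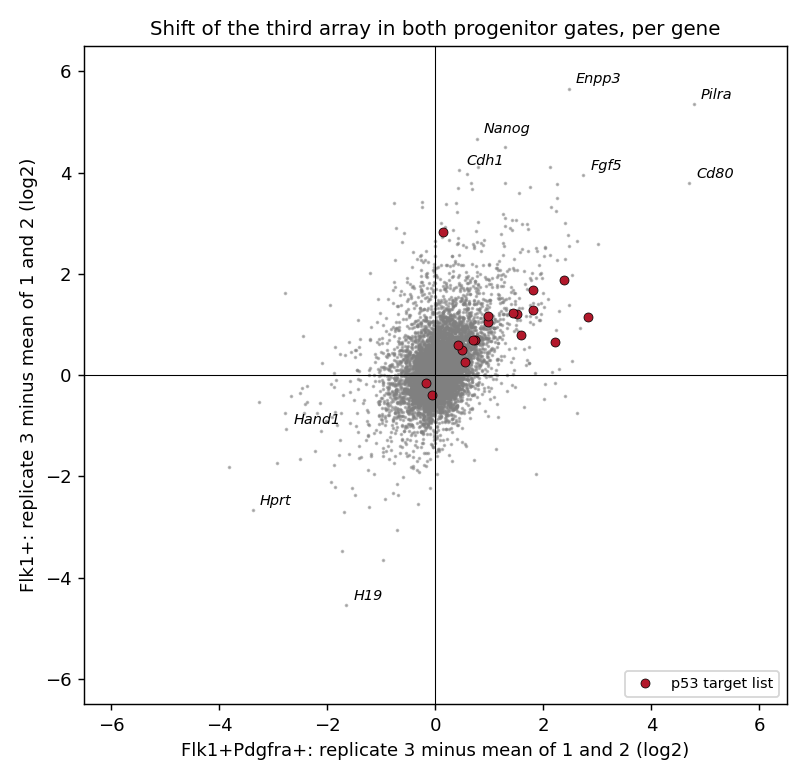
Shift of replicate 3 from the mean of replicates 1 and 2 (log2) for each of 14860 genes, Flk1+Pdgfra+ on the horizontal and Flk1+ on the vertical axis, with genes of the p53 target list in red. Hprt lay at -3.38 and -2.67, Pilra at 4.78 and 5.34, and of the 212 genes shifted by over 1 in both populations 168 moved up in both, 35 down in both and 9 apart.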

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

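No further test was run on this result, and its comparison with the transcript clusters that carry exactly 1 gene symbol was chosen after the result was seen. The transcript clusters without exactly 1 symbol were left out of every comparison of named genes, and they were looked at because they are measured and not otherwise reported on. The same limma model was fitted to all 23332 transcript clusters, with p-values adjusted over all of them. Of these 8336, 267 differed between Flk1+Pdgfra+ and Flk1+ at an adjusted p under 0.05, 77 higher and 190 lower. Between cTnT+ and Flk1+Pdgfra+ 1904 differed, 631 higher and 1273 lower, and between cTnT+ and Flk1+ 2357 differed, 574 higher and 1783 lower. At least 2-fold changes numbered 89, 572 and 908. The shares past the threshold, 3.20%, 22.8% and 28.3%, were below those of the transcript clusters with exactly 1 symbol, 8.12%, 38.2% and 36.5%. Both come from this wider adjustment and so differ from the shares of the 14860 genes given above. Their median level was also lower, 6.504 against 8.127. No explanation, technical or biological, was tested.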

How the results depend on the processing

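The fit with progenitor replicates 1 and 2 only and the fit of 6 arrays with the block were chosen after the results were seen. No list or named gene that was called reversed its direction under an alternative run here. Several lists that were not called did, among them sarcomere and Hox between the progenitors, as did Pdgfra between cTnT+ and Flk1+Pdgfra+. Which direction held more genes depended on scaling: between cTnT+ and Flk1+Pdgfra+ 2737 were higher and 3187 lower with median centring and 3062 and 3140 with quantile normalization, between cTnT+ and Flk1+ 2709 and 2713 with centring, and between the progenitors 917 and 862 with quantile normalization. Signal over background was not analysed here, so what dim genes limit was not tested. Between Flk1+Pdgfra+ and Flk1+, array weights gave 4521 higher, 3017 lower and 1184 genes changed at least 2-fold; the weights ran from 0.251 for Flk1+ replicate 3 to 7.73 for Flk1+ replicate 2. With progenitor replicates 1 and 2 only, 1148 genes were higher and 1024 changed 2-fold, and 10 lists were called. Leaving out an array gave 203 to 1306 higher, 461 to 1003 lower and 392 to 1022 with a 2-fold change, with 5 lists called without Flk1+Pdgfra+ replicate 3 and 10 without Flk1+ replicate 3. An estimated correlation called 0 lists in each of the 3 comparisons, and fry's test for either direction called 14 lists between the progenitors and 23 between cTnT+ and Flk1+Pdgfra+. Fry asks whether members change at all, not whether they change more than other genes, so its counts do not answer camera's question. Testing every transcript cluster gave 4076 lower between cTnT+ and Flk1+, where more features were tested. Genes higher in Flk1+Pdgfra+ than in both other groups numbered 1447 with array weights, and those of Flk1+ 1075. Leaving out an array gave 127 to 558 and 161 to 431 of these. The cause was not tested, except that fewer arrays were used when an array was left out. With the replicate block 685 genes were higher and 886 lower between the progenitors, and 1310 calls were shared with the fit without it. Lists that lost a call under some alternative numbered 6, 13 and 14 in the 3 comparisons, and named genes 23, 8 and 0. Of 15 genes that marked a group 4 did.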

Other observations

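The 6 gene lists of ribosome, hypoxia, epicardial, imprinted, retinoic acid and p53 genes were chosen after the results were seen, as were the tests of a shared difference, an earlier stage, array-wide labelling, p53 targets as a class, other cell types and carried-over progenitors, and the counts over assignments that part all pairs or keep the cTnT+ arrays in place. Genes of ribosome biogenesis fell between Flk1+Pdgfra+ and cTnT+: 20 of 20 fell, with a median of -1.51 (camera adjusted p = 9.34e-15, and 0.101 with an estimated correlation). Bop1, a factor of the large ribosomal subunit, fell by 2.09 on the log2 scale (adjusted p = 4.12e-05), Rrp12 fell by 2.06 and Polr1b, a subunit of RNA polymerase I, fell by 1.91. Against Flk1+ 19 of 20 fell (median -1.40, adjusted p = 1.07e-15, and 0.106 with an estimated correlation), and between the progenitors 0 of 20 were called by limma. Targets of hypoxia moved the other way, with 19 of 21 rising (median 1.64; adjusted p = 7.55e-08, and 0.101 with an estimated correlation), all but Egln3 and Stc2. Adm was 10.6-fold, Bnip3 10.3-fold and Vegfa 2.37-fold higher. Against Flk1+ 17 of 21 rose (median 1.37; adjusted p = 3.40e-06, and 0.107 with an estimated correlation). Between the progenitors Pdk1 and P4ha1 fell (median -0.19; adjusted p = 0.0377, and 0.530 with an estimated correlation). Pdk1, Slc2a1 and Slc2a3 are in the glycolysis list as well.

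Epicardial genes included Upk1b, which was 33.7-fold higher in cTnT+ than in Flk1+Pdgfra+ (adjusted p = 0.000174). In this list 6 of 15 rose and Dmkn fell (median 1.13, adjusted p = 0.0892). Against Flk1+ 6 rose (median 1.45; adjusted p = 0.0101, and 0.463 with an estimated correlation), and between the progenitors Lrrn4 rose (adjusted p = 0.353). Of 25 imprinted genes 13 rose and Mcts2 fell between Flk1+ and cTnT+ (median 0.71; adjusted p = 0.00432, and 0.106 with an estimated correlation). Dlk1, a fetal growth regulator, rose by 3.81 and Plagl1 by 4.56 there. Between Flk1+Pdgfra+ and cTnT+ 9 rose and Phlda2, Impact, Magel2 and Mcts2 fell (adjusted p = 0.0892), and between the progenitors Peg3, Dlk1, Phlda2, Asb4 and Magel2 rose and Igf2 fell (adjusted p = 0.0750). Of 11 retinoic acid genes Crabp1 and Rbp4 were higher in Flk1+Pdgfra+ than in Flk1+ (median 0.43; adjusted p = 0.0377, and 0.349 with an estimated correlation). The list did not pass in the other comparisons (adjusted p = 0.665 against Flk1+Pdgfra+, where Crabp2 and Rbp4 rose and Cyp26a1 fell, and 0.564 against Flk1+, where Crabp1 rose as well and camera pointed up and fry down). Of 19 p53 targets Pmaip1 alone was called between the progenitors (adjusted p = 0.114), and the list did not pass against Flk1+Pdgfra+ (Sesn1, Ddit4 and Fas rose, Pmaip1, Gtse1 and Aen fell, adjusted p = 0.665) or Flk1+ (Sesn1 and Fas rose, Sesn2, Gtse1 and Aen fell, median -0.068, mean 0.038, adjusted p = 0.564).

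The third array of both progenitor populations stood apart from the first and second, with Hprt at 7.02 against 10.4 in Flk1+Pdgfra+ and Nanog at 10.99 against 6.21 and 6.43 in Flk1+. The largest median shift of any of 20 chromosomes reached in both populations was 0.0493, which argues against a gained or lost chromosome. An array-wide difference in labelling or normalization cannot be told apart: the median absolute shift of the 8 reference genes other than Hprt was at most 0.0948, but RMA had already brought the arrays to one distribution and Hprt was left out after its shift was seen. Of 212 genes shifted by over 1 in both populations, 95.8% shifted the same way, but 906 genes shifted so far in Flk1+ and 395 in Flk1+Pdgfra+, and the epithelial median shifted by 1.99 in Flk1+ and 0.041 in Flk1+Pdgfra+. Candidate explanations are a difference shared by the third cultures for the shared part, if the numbers name cultures, and an earlier stage of differentiation. For the latter, 8 of 8 list medians moved in the direction it needs, such as streak genes by 0.35 in Flk1+Pdgfra+ and 0.90 in Flk1+. The lists and directions were chosen after the shifts were seen, so this tally restates them and decides nothing. It also leaves out other shifts, such as Hprt (-3.38 and -2.67) and smooth muscle genes (median 0.51 and 0.65).

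Targets of p53 were higher on the same arrays, with a median shift of 0.98 in Flk1+Pdgfra+ and 0.92 in Flk1+ and 16 of 18 up in each. These medians were at the 100th percentile of 10000 random lists matched on expression in both populations, whose medians ran from -0.091 to 0.14 and -0.11 to 0.16. Each shift rests on 1 array and on genes that vary together (estimated correlation 0.535), which the random lists leave out, and it was not particular to p53: stress and immediate early genes (0.50 and 0.51), smooth muscle (0.51 and 0.65) and retinoic acid genes (0.48 and 0.49) shifted up as well. A p53 or wider stress response in the third cultures may be the source, and an earlier stage stays open: the targets were higher by 0.49 in cTnT+ than on the first and second Flk1+Pdgfra+ arrays, but this later culture differs in composition and no stage before the progenitors was measured. Whether the third cTnT+ array carries the same difference stays open, since its median shift of 0.22 was above the random range (-0.10 to 0.14) and below the 0.5 set for the test. H19, Plagl1 and Slc38a4 were low, and the other 22 imprinted genes had median shifts of -0.020 in Flk1+Pdgfra+ and 0.31 in Flk1+ (percentiles 18.7 and 100). The genes left out were the lowest of the list, which raises these medians. The test therefore does not decide on imprinted genes as a class. It shows only that the other 22 were not low as a set in Flk1+.

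Genes of vessels and matrix, and some of blood such as Hba-x, were higher in cTnT+ than in Flk1+Pdgfra+, and the labels name no sort for cTnT that would remove other cells. Of the members that rose, 81.8% of the endothelial genes peaked on replicate 2, 100% of the matrix genes on replicate 3 and 75% of the haematopoietic genes on replicate 3, while 12 of 12 sarcomere and 5 of 8 smooth muscle genes peaked on replicate 1. The haematopoietic risers are less clear, since their median level was highest on replicate 1 (8.51, against 8.06 and 8.28). Cells of other types in proportions that differ between arrays may be the source, with Cdh5 at 11.5 to 12.3 and Hba-x at 12.3 to 13.1. Flk1+Pdgfra+ progenitors carried over unchanged could at most hold the endothelial genes at the Flk1+Pdgfra+ level. These genes were higher in cTnT+ by a median of 1.76 (lower end of the 95% interval 0.94, with members taken as independent) and 11 of 18 rose. That argues against such cells alone as the source, though the list was not called with an estimated correlation (0.525). The median restates the rise to be explained, which was seen before the question was put, and is no separate evidence. In Flk1+Pdgfra+ 7 of 18 endothelial, 6 of 17 matrix and 4 of 17 haematopoietic genes lay above the array median, which does not show expression because probes differ, and 2 matrix genes are in another list.

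Other splits of the arrays were counted for each comparison. The 10 splits of 6 arrays into 3 and 3 are too few for a share under 0.05: 1 of 10, the real one, gave as many genes in each comparison. The real counts were 1562, 6126 and 5827 genes, with 648, 2319 and 2099 changed 2-fold, and the highest other split gave 0 in each. Of the 4 splits that part all pairs in the progenitor comparison, the highest other gave 0. Each other split puts arrays of both populations together, so real differences enter the spread and lower the counts. The counts of 0 therefore do not speak against chance. For the genes higher in a population than in both others, 1 of 100 assignments gave as many as the 383 of Flk1+Pdgfra+ (highest other 52). As many as the 324 of Flk1+ came from 2 assignments (highest other 2207), and as many as the 2498 of cTnT+ from 1 (highest other 59). Most other assignments mix cTnT+ arrays with progenitor arrays, so that differences between populations enter the spread and lower the counts. These shares therefore do not exclude chance for any of the 3 sets. With the cTnT+ arrays kept in place the progenitor arrays have 10 splits, too few for a share under 0.05, and apart from the real split and its mirror the highest was 0. The other splits here mix both progenitor populations, which lowers their counts in the same way. Of the 53 assignments that part all progenitor pairs, 1, the real one, gave as many in each set, and the highest others gave 52, 86 and 59. Assignments that only exchange whole groups were not drawn. The assignment with 2207 had the 3 cTnT+ arrays in the place of Flk1+ and did not part all pairs, which points to the structure of the samples.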
